A study of Mus musculus with 16 samples.

How the data were processed

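Tail DNA of 8 mice of a family and of a reference male was hybridized to a custom Agilent oligonucleotide array in 2 colours, on 16 arrays over 4 slides. Each mouse appeared once in Cy3 and once in Cy5, per the labels. The scanner files were made with Feature Extraction 10.7.1.1 and protocol CGH_107_Sep09 on a design of build mm9, per the file headers. The deposited red and green signals are intensity values on a linear scale, background-subtracted, detrended and dye-normalized with linear factors, per the file headers. Each array held 118496 spots, of which 111933 were probe spots. The median background-subtracted signal was 1089 to 2023 in red and 705 to 1400 in green, the scanner's spread of differences between neighbouring log ratios was 0.0995 to 0.161, and no probe spot was saturated. The log ratios in the scanner files are log10 of the red over the green processed signal, not turned for the dyes, per the file headers. The authors' value table is on a log2 scale and correlated with the scanner's log ratio at 0.972 to 1.00 once the latter was turned to the channel labelled mouse over the channel labelled reference. Its column medians were between -0.0014 and 0.019, and it holds a further correction that is not given in the sources used here.

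Log2 ratios were computed from the processed signals and turned to labelled mouse over labelled reference, and 85 to 185 outlier spots per array were left out. Spots of a probe were averaged, each array was centred on its median with no loess or quantile step, and the 2 arrays of a mouse were averaged. The difference between the orientations divided by 2 gave the technical error and, searched in the same way, the false calls. An error that follows the DNA of a mouse into both of its arrays cancels in this difference and is not counted. The direction of every ratio comes from the labels. Signals of each channel were also examined separately, relative to that channel's median probe, and they contradict the labelled dyes or the labelled sexes, as the report describes. Groups were kept as labelled.

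Calls were made per mouse by an interval search on probes in map order. The interval with the largest sum of log2 ratio over noise SD, divided by the square root of the probe number, was taken while this score was at least 6. Calls needed 3 probes, a mean of at least 0.25 in size, the same sign in both orientations and no step over 100 kb. The noise SD was the scaled median absolute deviation of differences between neighbouring probes, divided by the square root of 2. Calls of different mice that shared a probe became 1 region. A mouse carried a region at a mean of at least 0.25 in the region's direction with both orientations on that side. A region was new in progeny when a pup carried it, neither parent did, and the pup lay at least 0.25 beyond each parent and beyond both in each orientation. Region means of progeny and parents were compared by exact permutation over 28 splits, two-sided. Probes were tested with limma 3.58.1 in R 4.3.3 (lmFit, eBayes, Benjamini-Hochberg) with 1 value per mouse, as progeny against parents and as the family against 0. Shares of pups are given with exact Clopper-Pearson 95% intervals. Other steps ran in Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and numba 0.67.0.

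The search was tested on simulated data, stretches of known shift added to the difference between orientations of each mouse over the 107902 probes. It found 93.5% of stretches of 3 probes shifted by 0.3, 99.0% of stretches of 5 probes shifted by 0.3, and all of those with 20 or 100 probes. These shares hold for the noise of that difference, in which an error shared by the arrays of a mouse cancels. In the values searched, the noise SD of pup 5 was 0.138. At that noise a shift of 0.3 over 3 or 5 probes alone scores below 6. The shares therefore do not show how often such stretches are found in pup 5. In simulated data of 107902 probes, limma recovered 47 of 50 probes shifted by 0.5 in the comparison of the family with the reference, with 5 false calls. The noise simulated for limma was independent between mice with 1 SD per probe, which the values of these mice are not.

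Regions named in the text followed a rule fixed before the data were examined. It took up to 12 regions new in progeny by their difference from the nearer parent, and the 12 other regions with the largest mean in size among those of at least 5 probes. The chromosome 14 stretches and the regions named for the sire against the dam were chosen after their values were seen. Alternatives covered background correction (normexp with an offset of 50, run on median signals because the files have no mean signals), the authors' values, centring, thresholds, dye orientations, dim probes, probe distance, segmentation, merging, slide and left-out mice. Alternatives chosen after seeing the data were longer and stronger calls, a correction for probe length, and scan day. Not run were the correction for GC content and its limma counterpart, which need the mm9 sequence, and the overlap with gene lists fixed beforehand, which needs gene names on mm9.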

Results

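Copy number was measured by comparative genomic hybridization on two-colour oligonucleotide arrays, on which the DNA of a mouse and a reference DNA compete for the same probes. The mice were a C57BL/6 family of a sire, a dam and 6 pups, and the reference was tail DNA of a male of the same colony. The series title places the family in a study of males kept under gamma rays at 1 mGy per day for 400 days, whereas the design text calls this sire non-irradiated, so the sire's exposure is not settled. No family of another sire was among these samples, and no effect of exposure could be compared. The array was the second of 2 screening steps and carried dense probes around loci that a first screen of the same mice had picked out. Each mouse was hybridized on 2 arrays with the dyes exchanged, which made 16 arrays, and the arrays of a mouse were counted as 1 replicate. The 107902 distinct probes had positions on genome build mm9, of which 96.5% lay in 466 tiled loci with a median length of 37.3 kb. The median distance between neighbouring probes was 93 bp, and 99.7% of the probes were well above background in both channels on all arrays. Where a value of a single mouse is followed by ±, this is the size of the difference between its dye orientations divided by 2, since each mouse is 1 DNA sample. The number of mice limits the precision of every comparison. The scanner files give positions and no gene names for the probes, and no annotation of this build was used here, so regions are described by position alone.

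The sex chromosomes were examined first, because they check the labels. In the channel labelled mouse, the 48 X probes had a median log2 signal between -0.87 and -0.71 relative to the median probe in all 8 mice, and the 3 Y probes lay between -1.88 and -1.56. The sire and the dam did not differ there, with X levels of -0.83 and -0.87 and Y levels of -1.56 and -1.66. In the channel labelled reference, which should hold the DNA of 1 male throughout, the X level was 0.16 on the sire's arrays and 0.15 on those of pup 5, against -0.89 to -0.71 on the arrays of the other 6 mice. The Y level in that channel was -5.28 for the sire's arrays and -6.18 for those of pup 5, towards the negative controls of the same arrays, at -7.30 and -8.05. For the other 6 mice it was between -1.80 and -1.60. For the sex chromosomes, the channel labelled mouse was thus the constant one, and the channel labelled reference was the one that varied between mice. The labels of the dyes and of the parents' sexes cannot all be right. A sire and a dam should differ in sex, and in the channel labelled mouse they did not, which argues against the dyes as labelled. Ratios below are still the channel labelled mouse over the channel labelled reference, which is also the direction of the authors' value table. With the dyes exchanged in the labels, the reading that these levels favour, each ratio above 0 is a loss of the family mouse. Each ratio below 0 is then a gain. That reading also needs the labels of the parents exchanged. The names sire and dam below mean the mice labelled so.

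**Figure D1:**
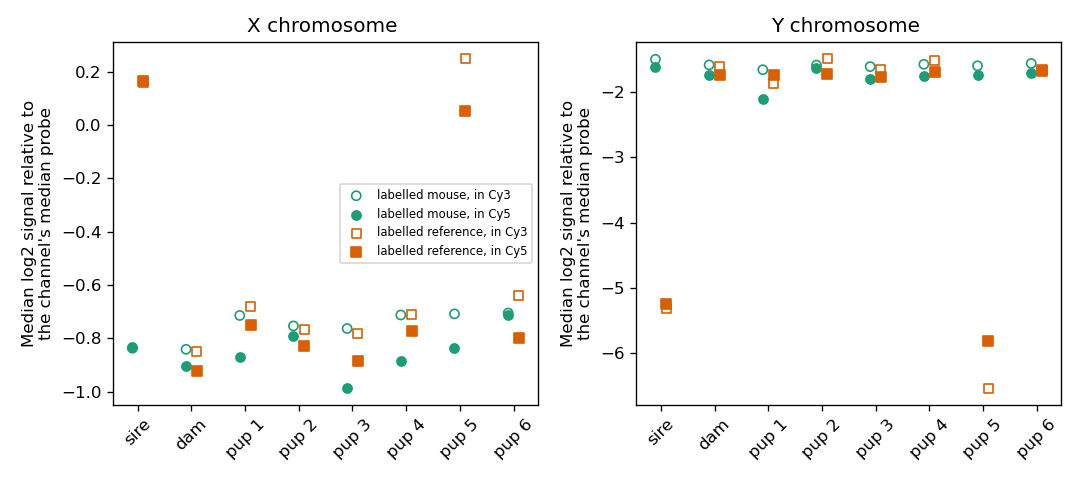
Median log2 signal of the X probes (left) and Y probes (right) relative to the median probe of the same channel, for each of the 8 mice on the horizontal axis, with circles for the channel labelled mouse, squares for the channel labelled reference, open symbols for Cy3 and filled ones for Cy5. The squares of the sire and pup 5 stand apart, at X levels of 0.16 and 0.15 and Y levels of -5.28 and -6.18.

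The first question was which loci of the family differed from the reference. The region with most probes was on chromosome 4 from 101109394 to 101271085, a stretch of 162 kb and 1110 probes. Its mean log2 ratio was -0.86 ± 0.04 in the sire, -0.87 ± 0.04 in the dam, -0.92 ± 0.04 in pup 2, -0.84 ± 0.05 in pup 3, -0.85 ± 0.06 in pup 4 and -0.90 ± 0.03 in pup 6. In pup 1 the mean was -0.53 ± 0.04 and in pup 5 -0.51 ± 0.05, nearer to 0 than in either parent along the whole stretch. The 20 probes on each side of it averaged 0.004 and -0.011 in pup 2. On chromosome 14, the 57 probes from 53664872 to 53764803 (99.9 kb) had means between 0.42 and 0.47 in all 8 mice. The region longest in kb followed it, from 53961688 to 54337811 (376 kb, 175 probes), with means between 0.18 and 0.25 in the 8 mice. A chromosome 10 stretch from 73561446 to 73615518, of 387 probes and 54.1 kb, differed in pup 4 alone, with a mean of 0.88 ± 0.01. A further 17.1 kb on chromosome 14 from 61805220 to 61822279, with 62 probes, had a mean of 0.26 ± 0.04 in the sire and of at most 0.08 in any other mouse. With the dyes read the other way, these values change sign and keep their size, so that the chromosome 10 stretch becomes a loss and the chromosome 4 stretch a gain.

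**Figure D2:**
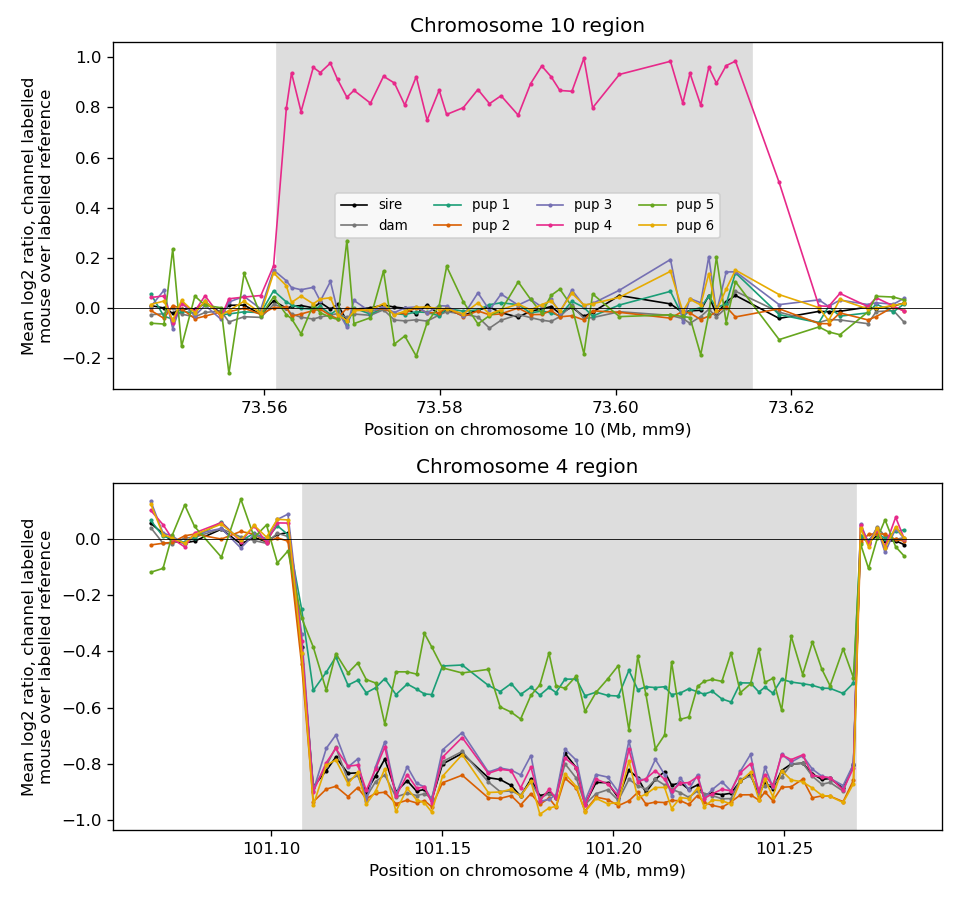
Mean log2 ratio of the channel labelled mouse over the channel labelled reference in consecutive groups of 10 probes on chromosome 10 (top) and 20 probes on chromosome 4 (bottom), with a line for each mouse, position in Mb on the horizontal axis and the called region in grey. Pup 4 alone has a region mean far from 0 on chromosome 10, at 0.88, while single groups of probes reach 0.27 in pup 5 and 0.20 in pup 3. On chromosome 4, pups 1 and 5 lie at -0.53 and -0.51.

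Shorter regions also stood far from 0. On chromosome 3 from 25421508 to 25454249, 14 probes had a mean of 1.41 ± 0.01 in the sire and 1.29 ± 0.02 in pup 5, against -0.05 to -0.002 in the other mice. On chromosome 11 from 36101013 to 36101829, 7 probes had means of 0.84 ± 0.08 in the sire, 0.95 ± 0.06 in the dam and 0.86 ± 0.08 in pup 5, and at most 0.02 in the other 5 pups. On chromosome 9 from 112702363 to 112703034, 5 probes had means of 0.84 ± 0.07 in pup 1 and 0.74 ± 0.06 in pup 4, with -0.02 in the sire and 0.002 in the dam. On chromosome 4 from 114585691 to 114585872, 5 probes had means of 0.33 ± 0.26 in the sire and 0.57 ± 0.23 in pup 5, so that the orientations differed widely. The sire's mean there rests on 1 probe, at 1.66, without which it was -0.0006.

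The interval search made 5567 calls over the 8 mice, which merged into 2762 regions with a median of 4 probes. The ratio was above 0 in 2061 regions and below 0 in 701, and without pup 5 in 1626 and 63. Only 83 regions had at least 20 probes, and 75 of these had their largest mean in pup 5. The number of calls differed widely between mice, with 56 in pup 2, 85 in the sire, 253 in the dam, 354 in pup 1, 851 in pup 4, 1167 in pup 6, 1325 in pup 5 and 1476 in pup 3. In the difference between dye orientations, where a copy number difference cancels, the same search made 53 to 142 calls per mouse, and 11 to 24 once the dye bias shared by all mice was taken out. In the sire the 126 false calls exceeded the 85 calls, but 11 false calls were left once that dye bias was taken out. None of those false calls had 20 probes or more, against 106 of the calls, of which 74 were in pup 5. An error that both arrays of a mouse share cancels in that difference too, so the false calls do not show how many calls are real. The noise between neighbouring probes was 0.138 in pup 5 and between 0.044 and 0.069 in the other mice. An alternative chosen after seeing the data, with at least 20 probes and a mean of at least 0.4 in size, left 6 regions: the chromosome 4 and chromosome 14 stretches described above, 386 of the chromosome 10 probes, a window of 23 probes on chromosome 3 from 25415719 to 25457053, a window of 20 probes on chromosome 11 from 36100017 to 36101914, and 39 probes on chromosome 14 from 54224024 to 54279592. Without pup 5 the search gave 1689 regions in all.

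**Figure D3:**
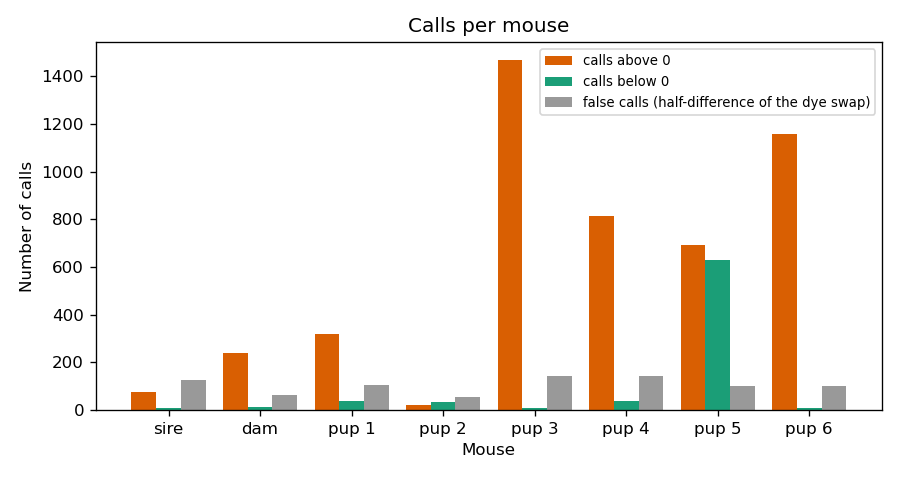
Number of calls (vertical axis) in each of the 8 mice (horizontal axis), split into log2 ratios above and below 0, with the false calls found in the difference between dye orientations divided by 2. Pup 3 had 1468 calls above 0, and pup 5 had 694 above and 631 below 0.

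The study looked for changes in pups that neither parent carries. The largest by its difference from the nearer parent was the chromosome 10 stretch of pup 4, whose mean lay 0.88 beyond that parent. It was 37.2 SD from the other 7 mice, which had a mean of 0.001 and an SD of 0.024. In SDs, 36 probes on chromosome 12 from 16976791 lay further, at 43.2 in pup 5, with a mean of -0.27. The chromosome 9 stretch of pups 1 and 4 lay 0.84 beyond the nearer parent. Being the most extreme of 8 mice has an exact one-sided p of at least 0.125, so a rank test cannot single out a pup in this design. By the fixed rule 1496 regions were new in progeny, of which 1350 were so in 1 pup. They counted 1138 in pup 5, 293 in pup 3, 180 in pup 6, 81 in pup 4, 4 in pup 1 and 2 in pup 2, and had a median of 6 probes. Pups 3, 4, 5 and 6 were scanned on another day than both parents, and pups 1 and 2 on the parents' day. The number of new regions can therefore not be told apart from an effect of scan day. After the chromosome 10 and 9 stretches, 9 of the 10 regions with the largest differences from the parents were 3 or 4 probes seen in pup 5 alone. The largest of these was on chromosome 4 from 30862763 to 30863130, at -0.72 ± 0.09, followed by chromosome 19 from 16731477 to 16731713 and chromosome 12 from 86084734 to 86084827, at -0.71 ± 0.01 and 0.71 ± 0.02. The remaining region, on chromosome 11 from 121622750 to 121622849, had means of 0.78 ± 0.09 in pup 3, 0.66 ± 0.16 in pup 4 and 0.66 ± 0.22 in pup 6. With normexp background correction pup 3 came to 0.44 there, and pup 5 to -0.44 on chromosome 19. Without pup 5 there were 427 new regions, and among the mice scanned on the parents' day (sire, dam, pups 1 and 2) there were 14, by alternatives of which the second was chosen after seeing the data. The chromosome 4 stretch is not among the new regions, because the rule counts it as carried by both parents.

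Regions shared by a parent and progeny show what may have been passed on. The chromosome 14 stretch and the chromosome 4 stretch were carried by both parents and all 6 pups, and were the only regions carried by all 8 mice. The reference was 1 animal, so a region off the same way in all 8 mice may also be a variant of the reference, with nothing passed on. The chromosome 11 region of 7 probes was carried by both parents and by 1 of 6 pups, and the chromosome 3 region by the sire and 1 of 6 pups. The chromosome 14 stretch of 62 probes was carried by the sire and by none of the pups, but without 1 probe that was also high in pup 5 the sire's mean was 0.23, under the 0.25 needed. In all, 148 regions were carried by a parent and at least 1 pup, with 13 from the sire only, 116 from the dam only and 19 from both. Of the 23 sire-only regions, pups carried 18 of 138 possible copies, 13.0% (exact 95% interval 7.92 to 19.8%). Of the 13 with a pup, 7 were carried by the sire and pup 5 alone and held probes at 1 or more in these 2 mice and within 0.25 of 0 in the other 6. These 2 are also the mice whose Y ratios stood apart, and the count was not corrected for sex. Leaving out the 8 sire-only regions with such probes gave 11 of 90, 12.2% (6.26 to 20.8%), a choice made after the values were seen. Of the 118 dam-only regions, they carried 400 of 708, 56.5% (52.8 to 60.2%). These intervals treat regions and pups as independent, which the pattern shared between mice does not bear out. None of the dam-only regions had 20 probes or more. Centring each probe on the median of the 8 mice left 20 shared regions, with 5 dam-only and 28 sire-only regions in all. In the dam-only regions among the 12 with the largest difference between the parents, the sire was above 0 too, at 0.14 to 0.22. The 56.5% can therefore not be read as the share passed on by the dam.

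Between progeny and parents, limma found no probe that differed among 107901 tested (6 pups against 2 parents, Benjamini-Hochberg, two-sided), with 565 at an unadjusted p under 0.05. The chromosome 11 region from 36101013 had a mean of 0.15 ± 0.35 (SD, n = 6) in progeny against 0.90 in the parents and an exact permutation p of 0.0714. No region mean had a smaller p, and the smallest p that the 28 splits allow is 0.0357. After Benjamini-Hochberg correction over the 2762 regions every p was 1. Without pup 5, which carries the region, limma called exactly the 7 probes of the chromosome 11 region, all lower in progeny (the region mean in 5 of 5 pups) by 0.64 to 1.08 on the log2 scale and with adjusted p between 0.000148 and 0.00929. The parents and pups 1 and 2 were scanned on 1 day and the other pups on another. With scan day as a block limma called no probe (298 at an unadjusted p under 0.05), and within the day of both generations 2 probes were called, both in the chromosome 11 region, with limma's adjusted p of 0.0294. Over all alternatives the smallest adjusted p ranged from 0.000148 to 1. With slide as a random block limma called no probe (354 at an unadjusted p under 0.05). In simulated data of the same spread for this comparison, 48 of 50 probes moved by 1 and 21 of 50 moved by 0.5 were recovered, with 9 false calls. The simulated noise was independent between mice with 1 SD per probe, whereas the mice here shared a pattern and differed in noise. The simulated recovery therefore does not give the power of the real comparison.

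The family against the reference gave 2683 probes past limma's adjusted p of 0.05 over the 8 mice, 1478 with ratios above 0 and 1205 below. The chromosome 4 stretch held 1102 of the 1205 below 0. The chromosome 14 stretch held 56 of those above 0, and the 178 probes of the next 1 Mb held a further 98. The probe A_67_P19021392 on chromosome 14 from 53758406 to 53758465 had the smallest adjusted p, 1.63e-06, at 0.54 (SE 0.016) with the same sign in all 8 mice. The reference is 1 animal, so its own spread is left out, and a variant of its own would move all 8 mice alike. In limma the 8 mice were treated as independent, though they are parents and their pups, with a correlation of 0.895 between pups 3 and 6. The p-values of limma here therefore measure how far values repeat within this family. Slide as a random block gave 2587 probes. Leaving out pup 5 gave 10184 (6935 above and 3249 below 0). Leaving out the dam gave 1618 (490 and 1128), pup 1 1654 (520 and 1134), pup 3 1610 (452 and 1158), pup 4 1574 (452 and 1122), pup 6 1649 (524 and 1125), the sire 2096 (943 and 1153) and pup 2 2946 (1734 and 1212). The number above 0 thus rests on which mice are included.

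The sire and the dam differed by at least 0.25 in the region mean, with the same sign in both dye orientations, in 50 regions. None of these had 20 probes or more. The ratio as labelled was higher in the sire in 19 and lower in 31, which change places with the dyes turned. The largest difference was the chromosome 3 region, at 1.41 ± 0.01 in the sire and -0.02 ± 0.04 in the dam. A second chromosome 3 region from 132549431 to 132549910 had means of 0.84 ± 0.14 in the sire, 0.82 ± 0.01 in pup 5 and 0.01 ± 0.15 in the dam. Of its 3 probes, 1 was at 2.42 in the sire and 2.01 in pup 5, and the other 2 averaged 0.04 in the sire and 0.22 in pup 5. Next came chromosome 9 from 74330099 to 74330215, at 1.36 ± 0.12 in the sire and 0.55 ± 0.12 in the dam, and chromosome 4 from 139228263 to 139228348, at 0.27 ± 0.21 in the sire and 1.08 ± 0.07 in the dam. The pups' means ranged from 0.24 to 1.55 on chromosome 9 and from 0.04 to 1.15 on chromosome 4. On chromosome 4 the dam and pup 1 were highest and pup 2 lowest. Short regions on chromosome 6 from 52778896, chromosome 10 from 22555403 and chromosome 17 from 90108672 repeated this. Such differences can therefore not be taken as particular to 1 locus. With 1 mouse each, no test was made. Between 25 and 105 regions differed when each dye orientation was used alone.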

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

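The tests of the dye labels, of scan day, of the slide and of mixed DNA were chosen after the results were seen, and so was the matching of calls in the test of probe length. Dixon's gap ratio at the 95% level was used to find a pup far from the other 5. Among 8 measures per mouse, 5 had one, where chance gives about 1 in 20 for a measure, and these measures are not independent. The X and Y medians among them can stand apart by sex alone. Among the 24 named regions, 18 had one, but these regions were chosen for an extreme mean, so their number says nothing about chance.

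Pup 5 stood apart in its 74 calls of at least 20 probes, its noise of 0.138, its X median of -0.991, its Y median of 4.523 and its 1138 new regions. In the channel labelled reference, pup 5 was the only pup with X and Y levels near those of the sire. These were 0.15 and -6.18 in pup 5, against 0.16 and -5.28 in the sire. By these levels pup 5 was the only pup of the sex seen on the sire's arrays, so its X and Y medians read its sex. It also stood apart at the chromosome 3 region (1.289), the chromosome 11 region from 36101013 (0.861) and chromosome 4 from 114585691 (0.566, with orientations 0.23 on either side). Short regions where it stood above the other pups were chromosome 12 from 86084734 (0.708) and from 107499337 (0.619), chromosome 4 from 84861898 (0.676, with orientations 0.32 on either side of it), chromosome 1 from 3602126 (0.623), chromosome 2 from 26681622 (0.575), chromosome 3 from 101197976 (0.552) and chromosome 13 from 116123568 (0.547). Short regions where it stood below them were chromosome 4 from 30862763 (-0.718), chromosome 19 from 16731477 (-0.708), chromosome 5 from 74842218 (-0.654) and from 87415495 (-0.635), chromosome 16 from 69105531 (-0.582), chromosome 1 from 152497608 (-0.566) and chromosome 2 from 100627795 (-0.564). Pup 4 stood apart at the chromosome 10 stretch (0.88).

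The first pattern is that signal differing between mice lies mostly in the channel labelled reference. Of 166 regions with at least 5 probes and means spanning at least 0.5 between mice, 163 (98.2%) had the larger SD between mice in that channel, with medians of 0.163 against 0.084 in the channel labelled mouse. Most of the 166 had their largest mean in pup 5, and of the 32 that did not, 31 had the larger SD in that channel. Among the 516 shorter regions spanning as much, 450 (87.2%) had it, and 3 of the 24 named regions, each of 3 probes, did not. These were chromosome 11 from 121622750 (0.24 against 0.45 in the channel labelled mouse), chromosome 5 from 87415495 (0.23 against 0.27) and chromosome 19 from 16731477 (0.29 against 0.30). At the chromosome 10 stretch, the channel labelled reference of pup 4 was at -0.83 and the channel labelled mouse at 0.03. Right dye labels with different reference mice on different arrays are argued against by the X level of the dam, which differed from that of the sire by only -0.038 in the channel labelled mouse. An exchange of the dyes in the labels of all arrays may therefore account for the pattern, and it would make the chromosome 10 stretch a loss and the chromosome 4 stretch a gain. It also needs the parents' labels exchanged, since in the channel labelled reference the Y level of the dam's arrays was 3.60 above that of the sire's.

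The second pattern is the many short calls in pups 3, 4 and 6, and those in pup 5. At least 1 of pups 3, 4 and 6 carried 1263 regions of fewer than 20 probes with ratios above 0. A scan-day effect as the whole cause is argued against by pup 1, scanned on the other day, whose mean over these regions was 0.140. Of that day, the dam had 0.114, the sire 0.084 and pup 2 0.013. Pups 3, 4 and 6 had 0.327, 0.245 and 0.303, above every mouse of the other day, while pup 5, of their own day, had -0.035. The regions came from calls in any mouse and were kept where pup 3, 4 or 6 carried them. Calls of pup 1 can be among them, so its mean is not free of selection. The sire, with 75 calls above 0 in all, was above 0 in 97.3% of these regions. Scan day as part of the cause stays open. Probe length was tried as a proxy for base composition. After correcting for it, 146 of the 3480 calls (4.20%) were overlapped by no call of the same pup, and 98 calls were added, which argues against probe length itself. Only 41.4% of the probes in these calls and 37.9% of the others were shorter than 60 bases, and probes of 1 length got 1 shared shift. The correction cannot reach base composition among probes of the same length, which stays open. Weak probes stay open, because the median signal of the probes in these calls lay at percentile 25.8 of all probes, between the bounds set beforehand. For pup 5 the slide is argued against by pup 6, which shared it and had a correlation of 0.034 with pup 5 over all probes. DNA quality was not measured, and the design gives no biological explanation that could be tested.

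The third pattern is that single pups differed from both parents over long stretches, pup 4 on chromosome 10 and pups 1 and 5 on chromosome 4. Waves along the probes of pup 4 are argued against, since the largest mean of any other stretch of 387 probes was 0.104 of the chromosome 10 mean, 0.09 in log2 units. Reference DNA mixed into a pup's DNA could pull the chromosome 4 ratio towards 0, but in pup 1 it would lower the chromosome 14 ratio to 0.31 or 0.22, depending on how the dyes are read, and that ratio was 0.47. In pup 5 it would bring the X median to -0.55 or -0.56, and that median was -0.99. A copy number change in these pups stays open as a hypothesis, and so do a wrongly assigned sample and mosaicism, which were not tested.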

How the results depend on the processing

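The scan-day, probe-length and 20-probe alternatives were chosen after seeing the data. Under 20 of the 21 alternatives that kept pup 4, a region new in pup 4 spanned at least 0.5 of the chromosome 10 stretch. With change points the stretch broke into 24 new regions holding 94.6% of its probes. Of 72 values of named regions under normexp, the authors' values or mode centring, 46 moved by less than the spread between orientations, 25 moved by more (17 of them with normexp) and 1 turned sign: pup 5 on chromosome 11 from 76356695, at -0.31 with normexp. On chromosome 5 from 87415495, pup 5 came to -0.37 with normexp. A single orientation cannot move beyond that spread, and the mean of pup 5 on chromosome 4 from 84861898 was 0.36 in Cy3 alone and 0.99 in Cy5 alone. The cause of the changes below was not tested. The 2762 regions became 1802 with normexp, 864 at a score of 10, 1325 at a size of 0.4, 1801 with at least 5 probes, 1581 with the mouse in Cy3 alone, 1830 with each probe centred on the 8 mice, and 6 with 20 probes and 0.4. Leaving out a pup gave 1689 to 2757. The 1496 new regions became 655 with normexp, 378 at a score of 10, 895 in Cy5 alone, 764 in Cy3 alone, 1 with 20 probes and 0.4, and 14 on the parents' scan day. Leaving out a pup gave 427 to 1524, the lowest without pup 5. The 148 shared regions became 59 at a size of 0.4, 48 with at least 5 probes, 264 in Cy5 alone, 294 in Cy3 alone, 75 with change points, 20 with probes centred on the 8 mice, 226 with stricter merging and 3 with 20 probes and 0.4. Leaving out a pup gave 148 to 155. The share of regions above 0 was 74.6%, and 87.7% with normexp, 82.1% with the authors' values, 68.7% with the mode, 91.4% at a score of 10, 56.2% with probes centred on the 8 mice and 96.3% without pup 5. The 50 differences between sire and dam became 25 in Cy5 and 105 in Cy3 alone. Progeny against parents stayed at 0 probes in 15 of 17 alternatives, with 2 within the parents' scan day and 0 to 7 when a mouse was left out, the 7 without pup 5. The 2683 probes of the family against the reference became 52328 in Cy5 and 40202 in Cy3 alone, and 1574 to 10184 when a mouse was left out, the highest without pup 5. Without the sire or the dam, the lone parent was assumed to vary like the pups. No paired analysis was possible because sire, dam and pups are different animals. The GC correction and the overlap with gene lists were not run. Though 99.7% of the probes were well above background on all arrays, the counts with normexp moved, so how far signal limits the short calls stays open. Leaving out dim probes gave 2693 probes for the family against the reference.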

Other observations

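The tests of the copy numbers and of Y-like sequence were both chosen after such values were seen.

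Autosomal probes high in the sire and pup 5 alone may hold sequence shared with the Y chromosome, since these are the mice whose labelled channels differ in Y signal. Counting autosomal probes of at least 1 in both of these mice and within 0.25 of 0 in the other 6 gave 19 probes on 10 chromosomes, and 0 for each of the other 27 of the 28 pairs of mice. Among them, 9 lay between 25421508 and 25454249 on chromosome 3, where the probe A_67_P11828393 from 25425639 to 25425698 reached 4.06 in the sire and 3.18 in pup 5. Others were single probes on chromosome 6 from 104241394 (2.15 and 2.14), chromosome 11 from 112961382 (1.78 and 2.25), chromosome 5 from 123598779 (1.66 and 2.15) and chromosome 14 from 61806290 (1.89 and 1.45), the last within the stretch of 62 probes that the sire carried. Of the 8 sire-only regions that held such a probe, 6 were regions of 3 to 5 probes with 1 of them, and their means without it ranged from -0.04 to 0.04 in the sire and from -0.07 to 0.22 in pup 5, where the other probes of 5 of them averaged at least 0.17. In the chromosome 3 region of 14 probes, the other 5 averaged 0.55 in the sire and 0.42 in pup 5. The sire's values in these 6 thus rest on the single probes, while in pup 5 other probes were raised too. The search picks intervals with a high score, and the noise of pup 5 was 0.138. The raised probes of pup 5 therefore decide nothing about sequence shared with the Y chromosome. No sequence was compared here.

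The sizes on chromosome 4 may be those of whole copies. With the dyes turned, 3 copies against 2 in the reference would give log2(3/2) = 0.58, and 4 against 2 would give 1.0. The sizes in pups 1 and 5 were within 0.078 of the first, while those in the other 6 mice were up to 0.16 short of the second, beyond the 0.15 set as a bound, so the values do not settle it.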
